A study of Drosophila melanogaster with 16 samples.

How the data were processed

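Trachea of Drosophila melanogaster larvae was profiled by RNA sequencing in 16 libraries, 4 each of smoke-exposed females, air-exposed females, smoke-exposed males and air-exposed males. Per the labels' protocols, RNA was isolated with the NucleoSpin RNA kit, libraries were made with the NEBNext Ultra RNA kit, and single reads of 75 bp were sequenced on a NextSeq500. Smoke came from 3R4F research cigarettes at 4 puffs per min for 60 min. Groups and replicate numbers were taken from the labels of the samples.

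The submitters' processing notes name the aligner STAR 2.6.0c and DESeq2 1.22.2, without saying how each was used. The only genome build those notes name is a human one, while all gene identifiers in the tables are FlyBase identifiers of the fly, so no coordinates are given here. The tool that counted reads, the use of strand, the annotation and any filter are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be separated. The authors deposited 1 table of normalised gene signal per sex, with 17559 genes and 8 libraries each, whose values are, judged from the values themselves, gene read counts divided by a size factor per library. They also deposited 1 table per sex of their own comparison, with log2 fold changes and p-values (raw and adjusted) that the authors computed, whose column names, per the file headers, are those of DESeq2. Their fold changes look shrunken, since fold over error is not the statistic given beside it.

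Normalised values were whole multiples of 1 read in each library, and 100% of values came out within 0.01 read of a whole number, so whole reads and size factors (0.750 to 1.30) were recovered. Recovered totals were 15036560 to 23434521 reads per library, and counting error is largest, relative to the value, for genes with few reads. Of 17559 identifiers 17253 matched the reference annotation (Ensembl BDGP6.54), which served only for names, chromosome arms and the order of neighbouring genes. The authors' comparison tables gave a symbol for 13779 genes, the reference added or replaced the name of 4414, and 211 had none. No value column was left without a sample. Over all 24 pairs of replicates within a group, counts differed by more than sampling noise (chi-square per degree of freedom 25.6 to 344), so no library was a copy of another of its group. Pairs across groups were not compared in this way.

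The deposited values were tested with limma 3.58.1 in R 4.3.3. Genes with a value of at least 10 in at least 4 of the 8 libraries of a sex were kept, values were transformed as log2(value + 1), and smoke was compared with air in each sex alone by limma with a mean-variance trend (two-sided). A fold change on this scale understates the change of low genes. Differences between the sexes in the response were tested in 1 model over the 16 libraries, as the female minus the male log2 change, for genes kept in both sexes. Because each sex was normalised in its own table, every test takes its differences within a table. Benjamini-Hochberg adjustment was applied over the genes tested, with a threshold of 0.05. Gene lists were tested with camera of limma at a preset correlation of 0.01, with adjustment over the 41 of 44 lists with at least 5 measured members. Camera with a correlation estimated per list and fry were run beside it. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes. Pearson and Spearman correlations and one-sided Fisher's exact tests describe the overlap of the sexes. Marker levels are CPM of recovered reads summed over a list.

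Designs, tests, the 44 gene lists, the alternatives and the rule for named genes were chosen before the data were examined. That rule took, per sex, the 10 largest rises and 10 largest falls among called genes that had a symbol, a group mean of at least 20 and groups that did not overlap, and up to 2 per direction among genes with only a CG number. From each list called or with at least 3 called members it took up to 4 called members with the smallest adjusted p, and after the values were seen this was limited to 2 per list. For the sex difference it took up to 6 genes of each sign by adjusted p, with the same floor on the mean. GstD1, Cyp6g1, the Hsp70 genes, roX1, roX2 and Y-linked genes were fixed in advance, and other genes fixed in advance are not analysed here. Lists of imaginal disc and posterior spiracle genes were added after the data were seen. Replicates 1 and 2 differ from replicates 3 and 4 in depth and in the style of their column names, which was seen in the data and used as a naming-style batch. Column names of replicates 3 and 4 also carry serial numbers. These run close together within a replicate number, across sexes and treatments, and were not used in the main tests.

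Alternatives were pseudocounts of 0.5 and 5, no filter or a filter of 50, libraries rescaled to the same upper quartile or the same total, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a replicate block, each library left out in turn, and a minimum fold of 2. edgeR called 1576 genes in females and 1008 in males, and DESeq2 2232 and 1971. Naming batch as a term, fits within each naming-style batch and list tests at the same total were added after the data were seen. Scripts were tested on simulated data made from the real means. With limma, 2-fold changes were recovered for 52.2% of changed genes in females (8769 genes), 50.7% in males (8612 genes) and 25.4% for the sex difference (8510 genes), and 4-fold changes for 90.9%, 87.9% and 78.8%. At 1.5-fold these shares were 5.97%, 14.9% and 7.46%. False genes made up 5.71%, 8.11% and 1.33% of calls with limma, 5.71% and 3.77% with edgeR in females and males, and 16.8% and 25.7% with DESeq2. A heat shock list moved 2-fold was called by camera in both sexes, with 0 other lists called. Genes were simulated independently of each other, so this run cannot show how often camera calls lists whose genes vary together.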

Results

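RNA was sequenced from isolated trachea of Canton S larvae, a wild-type laboratory strain of Drosophila melanogaster. The trachea is the branched airway of the insect. The larvae had been exposed to mainstream smoke of research cigarettes at 4 puffs per min for 60 min, or to air. Males and females were kept apart, which gave 4 groups of 4 libraries. Between 15036560 and 23434521 reads per library had been assigned to genes. Replicates 1 and 2 of each group held 19367755 to 23434521 reads and replicates 3 and 4 held 15036560 to 19431772. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The study compared smoke with air within each sex. Values below are normalised read counts, given as mean ± SD with n = 4 libraries per group, and log2 changes are smoke over air on the log2(value + 1) scale, given with ± SE. Adjusted p-values are from limma with Benjamini-Hochberg adjustment, or from limma camera for gene lists. Unless stated otherwise, in each sex where a named gene rose or fell all 4 smoke libraries lay on the same side of all 4 air libraries.

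The sex labels were checked first. The RNA of roX1, a male-specific part of the dosage compensation complex, stood at 1388 ± 418 in female air and 1735 ± 367 in female smoke, against 17531 ± 5094 in male air and 17479 ± 3589 in male smoke. The related roX2 RNA stood at 6.32 ± 3.86 and 11.7 ± 5.46 in females and at 242 ± 93.4 and 204 ± 22.7 in males. Both tables were normalised separately, so these levels are set side by side without a test. In males neither RNA passed the test of smoke against air. The log2 change of roX1 was 0.02 (limma adjusted p = 0.962) and its sign changed under other settings, and that of roX2 was -0.16 (limma adjusted p = 0.716). The 11 Y-linked genes of the list gave 10 reads in total over female air, 3 over female smoke, 39 over male air and 24 over male smoke.

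In female trachea exposed to smoke, limma called rises for 13 of 18 heat shock, 10 of 25 antioxidant, 13 of 32 glutathione S-transferase, 9 of 24 lipid and 8 of 17 JNK pathway genes, and falls for 18 of 36 cell cycle, 17 of 71 mitochondrial ribosomal protein and 8 of 11 salivary gland genes. In these lists 1 antioxidant, 2 glutathione S-transferase and 1 JNK gene fell, and 1 mitochondrial ribosomal protein gene rose. These lists passed limma camera at its preset correlation, and none passed with an estimated correlation (smallest adjusted p of any list 0.299). The largest rises belonged to neighbouring genes on chromosome arm 2R. The peroxiredoxin gene Prx2540-2 (FBgn0033518) rose from 92.7 ± 120.1 to 17481 ± 9956, a log2 change of 8.13 ± 0.76 (limma adjusted p = 0.000591). Its neighbour CG11825 (FBgn0033519) rose from 20.8 ± 19.8 to 6649 ± 777, a log2 change of 8.60 ± 0.47 (limma adjusted p = 6.15e-05). Sgs3 (FBgn0003373, chromosome arm 3L), which encodes a glue protein of the salivary gland, fell from 883 ± 537 to 29.9 ± 14.5, a log2 change of -4.75 ± 0.53 (limma adjusted p = 0.00141).

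The 4 genes Prx2540-2, CG11825, Prx2540-1 and CG12896 lie within 5 consecutive protein-coding genes, and all rose in females. The log2 changes of Prx2540-1 and CG12896 were 7.88 ± 0.63 and 8.23 ± 0.80. Prx2540-1 and Prx2540-2 are near-identical copies, so the split of reads between them is uncertain. Of the 25 measured genes of the antioxidant list, 10 rose, 1 fell and 14 were not called, and adjusted over the list alone 13 rose and 2 fell (limma camera adjusted p = 0.000159, and adjusted p = 0.366 with an estimated correlation). Among 32 glutathione S-transferase genes, which conjugate foreign compounds to glutathione, 13 rose, 2 fell and 17 were not called (limma camera adjusted p = 0.000273, and adjusted p = 0.583 with an estimated correlation). Adjusted over the list alone, 16 rose and 2 fell. GstD2 rose by 2.95 ± 0.30 and GstE1 by 1.94 ± 0.23 on the log2 scale. GstD1 did not pass the test (log2 change 0.61 ± 0.23, limma adjusted p = 0.0967). It did with DESeq2 (adjusted p = 0.042), and in limma with a replicate block (0.0131) or the naming-style batch as a term (0.00316). Over all settings other than DESeq2 its adjusted p lay between 0.00316 and 0.22. In males its log2 change was 0.49 ± 0.17 (limma adjusted p = 0.0858). The male adjusted p was 0.0271 with DESeq2, 0.0067 with a replicate block and 0.00984 with the naming-style batch as a term. It lay between 0.0067 and 0.174 over all settings other than DESeq2. Of 7 ABC efflux transporter genes, 3 rose and none fell, against 4 adjusted over the list alone (limma camera adjusted p = 0.0205, and adjusted p = 0.299 with an estimated correlation), with Mrp4 at 1.45 ± 0.14 and snu at 0.84 ± 0.14. Of 12 metal response genes, 5 rose and none fell, also adjusted over the list alone (limma camera adjusted p = 0.00634, and adjusted p = 0.299 with an estimated correlation). The metallothionein gene MtnE changed by 2.71 ± 0.36 and Tsf3 by 1.03 ± 0.17. Cytochrome P450 genes did not move as a list, with 5 of 61 higher and 1 lower (limma camera adjusted p = 0.22, and adjusted p = 0.932 with an estimated correlation), although Cyp6a20 rose from 2.16 ± 1.61 to 104 ± 44.6. Adjusted over the list alone, 4 P450 genes were higher and 1 lower.

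Heat shock genes rose in female smoke. Of 18 measured members 13 rose, none fell and 5 were not called, and adjusted over the list alone 14 rose (limma camera adjusted p = 4.69e-07, and adjusted p = 0.366 with an estimated correlation). The median log2 change of the list was 2.40. The co-chaperone genes stv and DnaJ-1 rose by 2.90 ± 0.23 and 2.69 ± 0.30, and stv stood at 2491 ± 730.3 to 18217 ± 3522. Hsp70Bb rose from 19.5 ± 25.4 to 357 ± 188 (limma adjusted p = 0.0126), although the Hsp70 copies are near-identical and the split of reads among them is uncertain. One female air library, replicate 2, held 55.2 of Hsp70Bb, against 1.26 to 19.9 in the other 3.

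**Figure D1:**
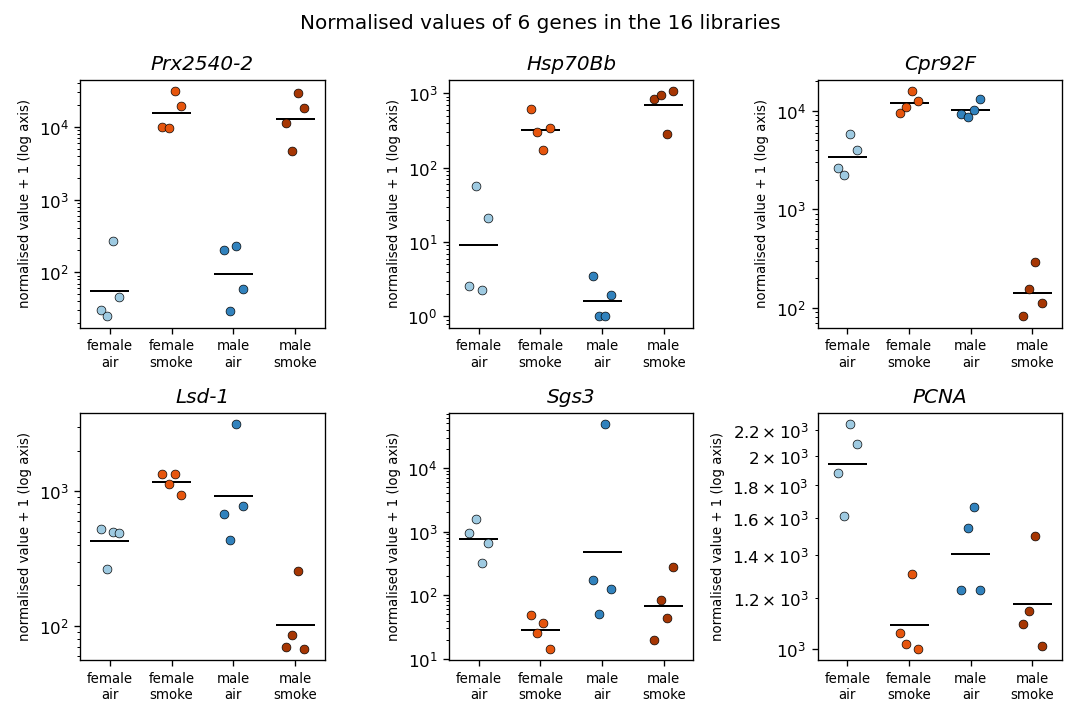
Normalised read counts (value + 1, log axis) of 6 genes in the 16 libraries, by sex and treatment, with a point per library and a bar at the group mean on the log scale. Prx2540-2 is higher in smoke in both sexes, with group means of 92.7 and 17481 in females, while Cpr92F is higher in female smoke and lower in male smoke.

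Genes of stress and immune signalling rose with smoke in females. Of 17 JNK pathway genes 8 rose and 1 fell, against 9 and 1 adjusted over the list alone (limma camera adjusted p = 0.000115, and adjusted p = 0.341 with an estimated correlation). The JNK target puc, which encodes a phosphatase that restrains the kinase, rose from 877 ± 173 to 4512 ± 339.6, a log2 change of 2.38 ± 0.14 (limma adjusted p = 7.36e-05). The pro-apoptotic gene rpr rose by 2.44 ± 0.21. Of 35 Imd and Toll pathway genes 12 rose and 2 fell, against 15 and 3 adjusted over the list alone (limma camera adjusted p = 0.000159, and adjusted p = 0.357 with an estimated correlation), including the transcription factor genes Rel (0.95 ± 0.16) and dl (0.71 ± 0.13). Of 13 JAK-STAT genes 4 rose, also adjusted over the list alone, and none fell (limma camera adjusted p = 0.0335, and adjusted p = 0.341 with an estimated correlation), with the cytokine genes upd2 and upd3 at 3.66 ± 0.53 and 2.47 ± 0.35. Of 21 insulin and TOR genes 7 rose and 1 fell, with the same counts adjusted over the list alone (limma camera adjusted p = 0.00587, and adjusted p = 0.299 with an estimated correlation). ImpL2, which encodes a secreted binder of insulin-like peptides, rose by 2.96 ± 0.14, and Thor, the 4E-BP translation repressor, by 2.40 ± 0.21. Of 25 autophagy and lysosome genes 6 rose and 1 fell, against 8 and 1 adjusted over the list alone (limma camera adjusted p = 0.0319, and adjusted p = 0.299 with an estimated correlation), with Atg1 at 1.42 ± 0.21. The JAK-STAT call was lost without female air 2 (0.106) or female smoke 3 (0.0621). The autophagy call was lost without female air 1 (0.057) and with libraries rescaled to the same upper quartile (0.0548) or total (0.0811).

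Lipid and chitin genes rose as lists in females. Of 24 lipid metabolism genes 9 rose and none fell, against 11 adjusted over the list alone (limma camera adjusted p = 7.07e-05, and adjusted p = 0.299 with an estimated correlation). The lipid droplet gene Lsd-2 rose from 3139 ± 256 to 6408 ± 109.6, a log2 change of 1.03 ± 0.07, and Lpin by 0.93 ± 0.11. Of 28 chitin metabolism genes 5 rose and 1 fell, against 7 and 1 adjusted over the list alone (limma camera adjusted p = 0.00316, and adjusted p = 0.299 with an estimated correlation), with Gasp at 0.64 ± 0.09 and Idgf2 at 0.76 ± 0.10. Of 65 structural cuticle protein genes 9 rose, also adjusted over the list alone, and none fell, and the list missed the threshold (limma camera adjusted p = 0.0912, and adjusted p = 0.858 with an estimated correlation). It passed with libraries rescaled to the same upper quartile (limma camera adjusted p = 0.00426) or total (0.00211), and so did the P450 list (0.0487 and 0.0411).

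Genes of cell division and mitochondrial translation fell in female smoke. Of 36 cell cycle and replication genes none rose, 18 fell and 18 were not called, and adjusted over the list alone 23 fell (limma camera adjusted p = 4.67e-10, and adjusted p = 0.357 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, fell from 1957 ± 275 to 1095 ± 144, a log2 change of -0.84 ± 0.13 (limma adjusted p = 0.00475), and Cdk2 changed by -1.04 ± 0.12. Imaginal disc genes, a list added after the data were seen, moved with them. Their summed level was 146 ± 49.8 CPM in female air and 33.5 ± 17.7 in female smoke, and 8 of 17 fell. Of 71 mitochondrial ribosomal protein genes 17 fell and 1 rose, against 26 and 1 adjusted over the list alone (limma camera adjusted p = 5.62e-09, and adjusted p = 0.299 with an estimated correlation). The falls were small, with a list median of -0.28 and log2 changes of -0.53 ± 0.09 for mRpL44 and -0.51 ± 0.08 for mRpS16. None of 64 oxidative phosphorylation genes was called by limma, also when adjusted over the list alone, or by edgeR, 1 was lower with DESeq2 and 5 at an unadjusted p under 0.05, while the list fell with a median of -0.17 (limma camera adjusted p = 0.00104, and adjusted p = 0.772 with an estimated correlation). Muscle markers, which belong to another tissue, moved the same way, at 11801 ± 5175 CPM in female air and 6907 ± 2293 in female smoke.

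Markers of other tissues differed between female smoke and air. Of 11 salivary gland markers 8 fell, none rose and 3 were not called, and adjusted over the list alone 10 fell (limma camera adjusted p = 2.35e-07, and adjusted p = 0.299 with an estimated correlation). Their summed level was 195 ± 127 CPM in air and 10.2 ± 5.002 in smoke. Among the 10 largest falls that the rule for named genes gave, 7 were glue genes, with log2 changes of -4.74 ± 0.57 for Sgs4, -4.76 ± 0.78 for Sgs5 and -3.39 ± 0.39 for Sgs1. Of 11 midgut and 19 muscle markers none was called by limma, over all genes or over the list alone, while both lists were lower (limma camera adjusted p = 0.00702, and adjusted p = 0.653 with an estimated correlation for midgut). For muscle, limma camera adjusted p = 0.03, and adjusted p = 0.841 with an estimated correlation. By edgeR none of these was called either, DESeq2 called 3 midgut markers and 1 muscle marker lower, and 4 and 1 were lower at an unadjusted p under 0.05. Midgut markers were highest in female air replicate 3, at 1456 CPM. The midgut call was lost without female air 1 (0.0647), female air 3 (0.152) or female air 4 (0.156), and with the same upper quartile (0.0548). The muscle call was lost without female air 1 (0.0666), female air 3 (0.125), female air 4 (0.0961), female smoke 2 (0.0685) or female smoke 4 (0.107), and with the same upper quartile (0.155) or total (0.115). The proteasome list, with none of 33 genes called by limma, edgeR or DESeq2 and 1 lower at an unadjusted p under 0.05, was lower (limma camera adjusted p = 0.0346, and adjusted p = 0.858 with an estimated correlation), and this call was lost without female air 2 (0.33), female air 4 (0.214), female smoke 1 (0.148), female smoke 2 (0.0539) or female smoke 3 (0.0788).

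In all, 1599 of 8877 genes tested in females passed an adjusted p of 0.05 in limma, 970 higher and 629 lower in smoke, and 426 of them changed at least 2-fold, 292 higher and 134 lower. All 4 smoke values lay above or below all 4 air values for 24.5% of the genes, against 2.86% by chance. The share of higher genes among calls was 60.7% as deposited, 37.5% with the same upper quartile (722 higher, 1201 lower) and 38.2% with the same total (644 higher, 1042 lower), and the median log2 change of all genes moved from -0.02 to -0.13 under both. Of 41 lists, 19 were called by limma camera and 19 by fry, and none with an estimated correlation, where 5 had an unadjusted p under 0.05. Of the 19 lists that camera called, fry did not call 4. These were oxidative phosphorylation (fry adjusted p = 0.297), the proteasome (0.477), and muscle (0.386) and midgut markers (0.146). No called list turned its direction under either scaling, and 3 of the 19 calls were lost with the same upper quartile and 2 with the same total. Within replicates 1 and 2 alone 12 genes were called, within replicates 3 and 4 799, and all 1599 genes had the same sign in both, although these libraries also chose them. The count of calls was 1052 without female air 4, 1003 without female smoke 3 and 994 without female smoke 4, and the lower genes alone numbered 345, 355 and 342 in these fits and 377 without female smoke 2. The count of all calls was 2514 with the naming-style batch of replicates 1 and 2 against 3 and 4 as a term, and 2906 with array weights.

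In male trachea exposed to smoke, limma called rises for 16 of 19 heat shock, 9 of 17 JNK, 5 of 18 Notch and 8 of 35 Imd and Toll genes. It called falls for 11 of 63 cuticle protein, 5 of 24 lipid, 9 of 58 P450 and 7 of 19 muscle marker genes, and for 1 of 9 fat body and 1 of 17 hemocyte markers, while 2 cuticle protein and 4 P450 genes rose. These lists passed limma camera at its preset correlation, and none passed with an estimated correlation (smallest adjusted p of any list 0.430). The cuticle protein gene Cpr92F (FBgn0038819, chromosome arm 3R) fell from 10321 ± 1957 to 158 ± 91.2, a log2 change of -6.17 ± 0.35 (limma adjusted p = 6.63e-05). The small heat shock gene Hsp26 (FBgn0001225, chromosome arm 3L) rose from 787 ± 667 to 21826 ± 6002, a log2 change of 5.14 ± 0.55 (limma adjusted p = 0.00148). Prx2540-2 and CG11825 rose by 7.09 ± 0.77 and 8.15 ± 0.49, and dyl, a zona pellucida domain gene expressed in epithelia, by 5.38 ± 0.80.

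Of 19 heat shock genes measured in males 16 rose, none fell and 3 were not called, and adjusted over the list alone 16 rose and 1 fell (limma camera adjusted p = 3.94e-15, and adjusted p = 0.43 with an estimated correlation). The gene stv rose from 1803 ± 272 to 23989 ± 4246, a log2 change of 3.73 ± 0.15. Hsp70 copies were near 0 in male air, so levels are given in place of folds. Hsp70Bc stood at 2.33 ± 0.766 to 621 ± 246 from air to smoke, and Hsp70Bbb had 0 in all 4 air libraries and 175 ± 77.1 in smoke. Of 17 JNK pathway genes 9 rose and none fell, also adjusted over the list alone (limma camera adjusted p = 0.000121, and adjusted p = 0.43 with an estimated correlation). The log2 changes were 2.12 ± 0.09 for puc and 0.95 ± 0.11 for kay, the Fos gene. Of 18 Notch pathway genes 5 rose and none fell, against 6 adjusted over the list alone (limma camera adjusted p = 0.00151, and adjusted p = 0.43 with an estimated correlation), with E(spl)mbeta-HLH at 1.49 ± 0.12 and mib1 at 0.54 ± 0.07. Of 35 Imd and Toll genes 8 rose and none fell, against 9 and 1 adjusted over the list alone (limma camera adjusted p = 0.00657, and adjusted p = 0.515 with an estimated correlation). The Imd inhibitor gene pirk rose from 53.2 ± 48.6 to 1255 ± 491 and Rel by 0.93 ± 0.15 on the log2 scale.

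Other signalling lists were higher in male smoke. Of 12 JAK-STAT genes 3 rose and none fell, against 6 and 2 adjusted over the list alone (limma camera adjusted p = 0.00657, and adjusted p = 0.43 with an estimated correlation), with the target gene Socs36E at 1.81 ± 0.16 and upd2 at 3.00 ± 0.40. Of 21 insulin and TOR genes 4 rose, against 7 adjusted over the list alone, and none fell (limma camera adjusted p = 0.00657, and adjusted p = 0.43 with an estimated correlation), with Thor at 2.52 ± 0.35 and rictor at 0.60 ± 0.07. Of 23 DNA damage and apoptosis genes 3 rose, also adjusted over the list alone (limma camera adjusted p = 0.00657, and adjusted p = 0.43 with an estimated correlation), with rpr at 1.88 ± 0.22 and the stress factor gene Xrp1 at 1.06 ± 0.11. Of 25 FGF and EGF pathway genes 5 rose and 1 fell, against 5 and 2 adjusted over the list alone (limma camera adjusted p = 0.0313, and adjusted p = 0.43 with an estimated correlation), with the FGF ligand gene pyr at 1.73 ± 0.16. Of 12 metal response genes 2 rose, against 4 adjusted over the list alone (limma camera adjusted p = 0.0455, and adjusted p = 0.43 with an estimated correlation), with MTF-1 at 0.47 ± 0.08. The FGF and EGF call was lost without male air 1 (0.0523) or male smoke 2 (0.0534). The metal response call was lost without male air 1 (0.0823), male air 2 (0.0983), male smoke 3 (0.109) or male smoke 4 (0.0538), and with a replicate block (0.0696). Of 25 antioxidant genes 6 rose and 1 fell, against 8 and 2 adjusted over the list alone, and of 30 glutathione S-transferase genes 3 rose and 2 fell, also adjusted over the list alone. Neither list was called in males (limma camera adjusted p = 0.0894, and adjusted p = 0.587 with an estimated correlation for the first, and camera adjusted p = 0.934 for the second), although Gclm, a subunit of the enzyme that starts glutathione synthesis, rose by 2.04 ± 0.21.

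**Figure D2:**
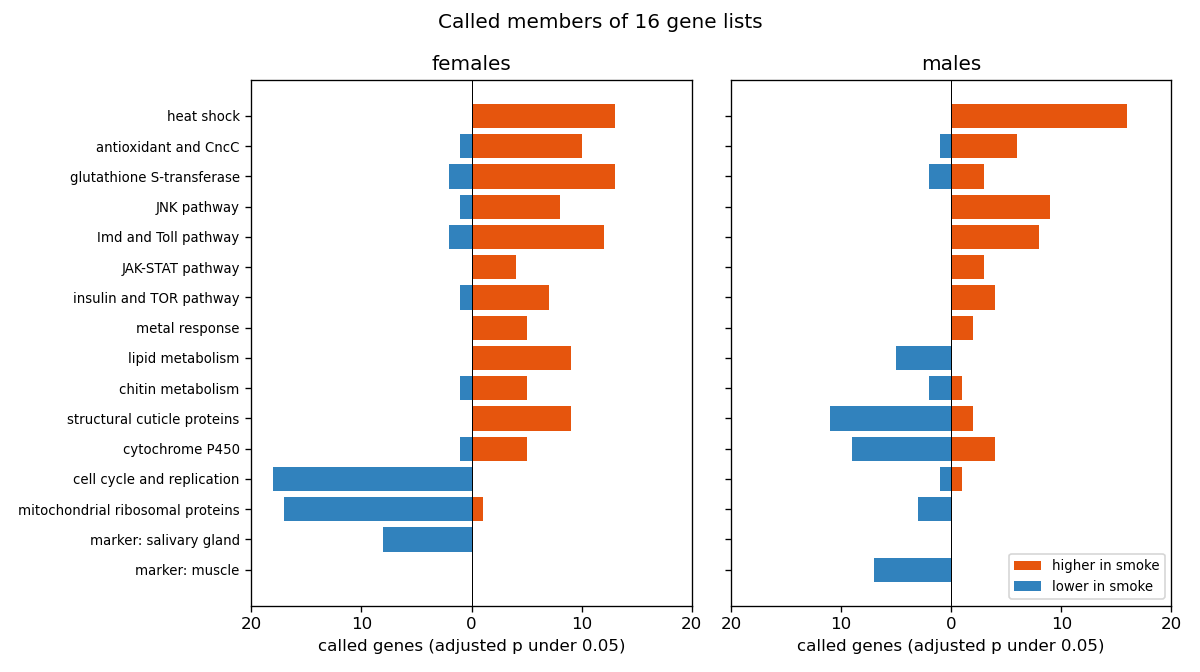
Number of genes called higher or lower in smoke in 16 gene lists, shown for females and males and chosen for display after the values were seen. Heat shock genes were called higher in 13 of 18 cases in females and 16 of 19 in males, and cell cycle genes lower in 18 of 36 cases in females and 1 of 36 in males.

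Cuticle genes fell in male smoke. Of 63 structural cuticle protein genes 11 fell, 2 rose and 50 were not called, with a list median of -1.39, and adjusted over the list alone 16 fell and 3 rose (limma camera adjusted p = 0.000121, and adjusted p = 0.43 with an estimated correlation). Cpr100A fell from 4218 ± 639.7 to 62.4 ± 35.2, a log2 change of -6.18 ± 0.31 (limma adjusted p = 4.46e-05), and Cpr62Bc by 6.93 on the log2 scale. Of 58 P450 genes 9 fell and 4 rose, against 13 and 4 adjusted over the list alone (limma camera adjusted p = 0.0313, and adjusted p = 0.642 with an estimated correlation). Cyp4c3 changed by -4.92 ± 0.61 and Cyp4ac3 by -2.99 ± 0.60. Of 24 lipid metabolism genes 5 fell and none rose, also adjusted over the list alone (limma camera adjusted p = 0.0309, and adjusted p = 0.587 with an estimated correlation). ATPCL, which makes cytosolic acetyl-CoA, changed by -0.55 ± 0.10, and outside the list the fatty acid elongase genes Elo68alpha and Elo68beta changed by -6.30 ± 1.15 and -5.67 ± 0.88. The P450 call was lost without male air 1 (0.0662), male air 3 (0.179), male air 4 (0.0653) or male smoke 2 (0.0504), and with the same upper quartile (0.147) or total (0.0994). The lipid call was lost without male air 3 (0.101) or male smoke 2 (0.0812), and with the same upper quartile (0.0511). Fat body markers, whose tissue stores lipid, moved with these lists, at 10644 ± 16170.2 CPM in male air and 669.6 ± 714 in male smoke.

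Markers of other tissues were lower in male smoke. Of 19 muscle markers 7 fell, against 16 adjusted over the list alone, and none rose (limma camera adjusted p = 1.69e-06, and adjusted p = 0.471 with an estimated correlation). Their level was 9737 ± 4055 CPM in air and 4771 ± 1835 in smoke. The limma call of the example TpnC47D was lost without male air 2 (0.0593), male air 3 (0.0668), male air 4 (0.0786), male smoke 1 (0.0803), male smoke 3 (0.0535) or male smoke 4 (0.0725), and that of Zasp66 without male air 2 (0.065), male air 3 (0.055), male air 4 (0.0532), male smoke 1 (0.0777), male smoke 3 (0.0674) or male smoke 4 (0.0606). With edgeR, Zasp66 also missed the threshold (log2 change -2.53, edgeR adjusted p = 0.0569). Of 9 fat body markers 1 fell, against 9 adjusted over the list alone (limma camera adjusted p = 0.00059, and adjusted p = 0.515 with an estimated correlation). This was the lipid droplet gene Lsd-1 (log2 change -3.19 ± 0.66, limma adjusted p = 0.0196), whose call was lost without male smoke 1 (0.0648) or male smoke 4 (0.0543). Of 17 hemocyte markers 1, the scavenger receptor gene crq, fell (log2 change -0.54 ± 0.08), also adjusted over the list alone (limma camera adjusted p = 0.000218, and adjusted p = 0.471 with an estimated correlation). Male air replicate 3 stood apart, with 7840 CPM of salivary, 34721 of fat body and 3104 of hemocyte markers, against 14.5 to 38.04, 1019 to 5376 and 1311 to 1396 in the other 3 male air libraries. Of 8 salivary markers none was called in males by limma, over all genes or the list alone, by edgeR or DESeq2, or at an unadjusted p under 0.05 (limma camera adjusted p = 0.0568, and adjusted p = 0.632 with an estimated correlation). None of 11 midgut and 11 neuron and glia markers was called by limma, over all genes or the list alone, or by edgeR, while 3 of each were lower with DESeq2 and 3 and 4 at an unadjusted p under 0.05. Both lists were lower (limma camera adjusted p = 0.0114, and adjusted p = 0.529 with an estimated correlation for neurons and glia). For midgut, limma camera adjusted p = 0.0313, and adjusted p = 0.587 with an estimated correlation, lost without male air 3 (0.0662), male smoke 1 (0.0694) or male smoke 2 (0.152), and with the same upper quartile (0.126) or total (0.0894).

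Mitochondrial and proteasome lists were lower in male smoke by small amounts. None of 63 oxidative phosphorylation genes was called by limma, also adjusted over the list alone, or by edgeR, while 6 were lower with DESeq2 and 9 at an unadjusted p under 0.05, at a list median of -0.22 (limma camera adjusted p = 7.98e-06, and adjusted p = 0.529 with an estimated correlation). Of 71 mitochondrial ribosomal protein genes 3 fell and none rose, against none adjusted over the list alone, at a median of -0.13 (limma camera adjusted p = 0.00381, and adjusted p = 0.471 with an estimated correlation). Of 33 proteasome genes 1 fell, against none adjusted over the list alone (limma camera adjusted p = 0.00039, and adjusted p = 0.587 with an estimated correlation). Muscle markers moved with these lists, as in females. Cell cycle genes gave 1 higher and 1 lower of 36 in males, with neither called when adjusted over the list alone (limma camera adjusted p = 0.675, and adjusted p = 0.939 with an estimated correlation).

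In all, 1178 of 8705 genes tested in males passed an adjusted p of 0.05 in limma, 774 higher and 404 lower in smoke, and 420 of them changed at least 2-fold, 149 higher and 271 lower. The groups did not overlap for 22.5% of the genes, against 2.86% by chance. The share of higher genes among calls was 65.7% as deposited, 45.9% with the same upper quartile (459 higher, 542 lower) and 48.7% with the same total (444 higher, 467 lower). Of 41 lists, 20 were called by limma camera and 19 by fry, and none with an estimated correlation, where 4 had an unadjusted p under 0.05. Of the 20 lists that camera called, fry did not call 7. These were P450 (fry adjusted p = 0.300), oxidative phosphorylation (0.138), proteasome (0.192) and lipid genes (0.177). The others were fat body (0.0749), neuron and glia (0.0965) and midgut markers (0.197). Within replicates 1 and 2 alone 146 genes were called, within replicates 3 and 4 11, and all 1178 had the same sign in both, although these libraries also chose them. The count of calls was 755 without male air 1 (219 lower), 524 without male air 2 (377 higher, 147 lower), 736 without male air 3 (521 higher, 215 lower), and 590 without male air 4 (440 higher, 150 lower). It was 478 without male smoke 1 (340 higher, 138 lower), 680 without male smoke 3 (449 higher, 231 lower) and 623 without male smoke 4 (419 higher, 204 lower). With the naming-style batch as a term it was 1967, and with DESeq2 1971. It was larger still with a replicate block, as given below.

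The smoke response differed between the sexes for 8 of 59 cuticle protein, 4 of 24 lipid and 4 of 57 P450 genes by limma, all more positive in females. The lists passed limma camera at its preset correlation but not with an estimated correlation (adjusted p = 0.225, 0.183 and 0.401), and the P450 list did not pass fry (adjusted p = 0.169). Cpr92F rose from 3659 ± 1637 to 12221 ± 2675 in females and fell from 10321 ± 1957 to 158 ± 91.2 in males, a difference of 7.99 ± 0.50 on the log2 scale, female minus male (limma adjusted p = 7.53e-07). The difference had the smallest adjusted p for CG4000 (FBgn0038820, chromosome arm 3R), with log2 changes of 1.61 ± 0.19 in females and -5.50 ± 0.28 in males (limma adjusted p = 7.38e-08). Cda5, a chitin deacetylase gene, gave 1.08 ± 0.18 and -2.19 ± 0.17, and Wnt6 gave 1.01 ± 0.23 and -1.96 ± 0.20. Agpat3, an acyltransferase gene of phospholipid synthesis, gave 0.44 ± 0.08 and -0.82 ± 0.08.

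**Figure D3:**
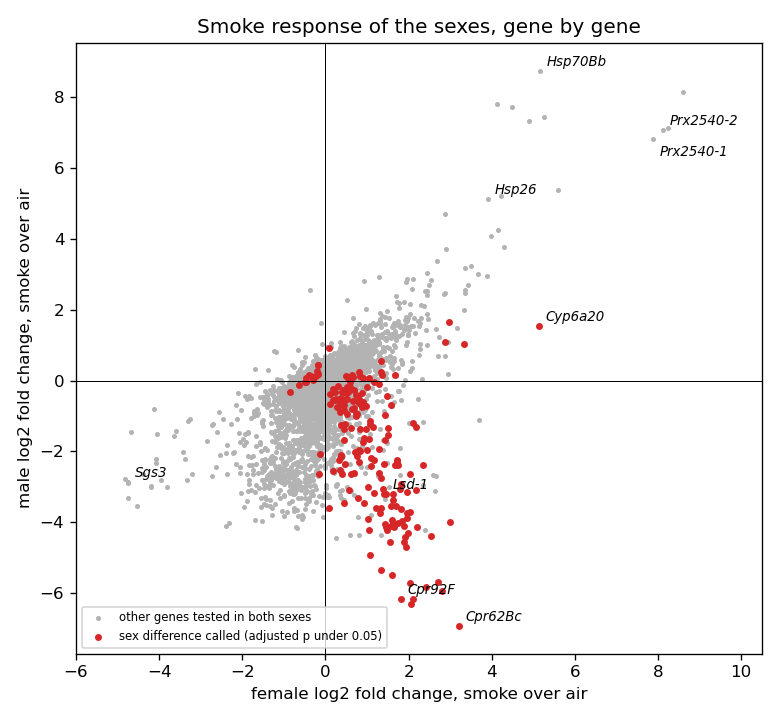
Log2 fold change of smoke over air for each gene tested in both sexes, females on the horizontal and males on the vertical axis, with red points for genes whose response differed between the sexes (limma adjusted p under 0.05). Cpr92F lies at 1.82 and -6.17, while Prx2540-2 lies at 8.13 and 7.09 and was not called different.

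Gene lists moved apart in the same test. Of 59 cuticle protein genes 8 responded more positively in females and none more negatively, against 12 adjusted over the list alone (limma camera adjusted p = 1.72e-10, and adjusted p = 0.225 with an estimated correlation). Of 24 lipid metabolism genes 4 did so, against 10 adjusted over the list alone, and all 24 differences were above 0 (limma camera adjusted p = 1.49e-11, and adjusted p = 0.183 with an estimated correlation). Of 57 P450 genes 4 did so, against 5 adjusted over the list alone (limma camera adjusted p = 3.95e-06, and adjusted p = 0.401 with an estimated correlation), of 28 chitin genes 3 against 5 (limma camera adjusted p = 4.46e-05, and adjusted p = 0.183 with an estimated correlation), and of 30 glutathione S-transferase genes 1 against 2 (limma camera adjusted p = 8.55e-05, and adjusted p = 0.401 with an estimated correlation). Fat body and hemocyte markers moved with them, each with 1 gene called and 1 adjusted over the list alone (limma camera adjusted p = 0.000109, and adjusted p = 0.401 with an estimated correlation for fat body). For hemocytes, limma camera adjusted p = 4.35e-08, and adjusted p = 0.292 with an estimated correlation. Cell cycle genes responded more negatively in females, with all 36 differences below 0 and 1 called, also adjusted over the list alone (limma camera adjusted p = 8.03e-12, and adjusted p = 0.354 with an estimated correlation). Heat shock genes responded less in females as a list, at a median difference of -0.85, and none of 18 was called by limma, over all genes or the list alone, or by edgeR, while DESeq2 called 5 and 6 had an unadjusted p under 0.05 (limma camera adjusted p = 5.25e-05, and adjusted p = 0.401 with an estimated correlation). Of the other lists called, 5 kept their camera call without any 1 library. More negative in females were mitochondrial ribosomal proteins (limma camera adjusted p = 0.000124, and adjusted p = 0.359 with an estimated correlation), the Notch pathway (limma camera adjusted p = 0.000478, and adjusted p = 0.359 with an estimated correlation), sex determination genes (limma camera adjusted p = 0.00226, and adjusted p = 0.225 with an estimated correlation) and the Wnt pathway (limma camera adjusted p = 0.00315, and adjusted p = 0.401 with an estimated correlation), and more positive was the antioxidant list (limma camera adjusted p = 0.00572, and adjusted p = 0.401 with an estimated correlation). Fry did not call several of these lists. They were heat shock (fry adjusted p = 0.154), glutathione S-transferases (0.154), fat body markers (0.154) and cell cycle (0.0668). Mitochondrial ribosomal proteins (0.0668), Notch (0.104), Wnt (0.169), antioxidant (0.172) and P450 genes (0.169) were also not called by fry. The pathway genes puc, rpr, Rel and Thor showed no called difference, with limma adjusted p-values of 0.553, 0.461, 0.985 and 0.945.

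Calls of the remaining 7 lists depended on single libraries. They covered UDP-glycosyltransferases, ABC transporters, autophagy, muscle markers and neuron and glia markers, more positive in females, and the FGF and EGF pathway and cytosolic ribosomal proteins, more negative. Camera adjusted p-values of limma were 0.0135, 0.0435, 0.0241, 0.0135, 0.0417, 0.0487 and 0.04 in that order, and the smallest adjusted p of any list was 0.183 with an estimated correlation. The first was lost without male air 1 (0.0782) or male air 4 (0.0613) and the third without male smoke 2 (0.0832). The ABC transporter call was lost without female air 1 (0.0852), female air 4 (0.0891), female smoke 2 (0.0763), female smoke 3 (0.0548), male air 1 (0.0756), male smoke 1 (0.0619), male smoke 2 (0.063) or male smoke 4 (0.0618), the muscle call without female air 2 (0.331), female smoke 3 (0.0859), male air 3 (0.086), male smoke 1 (0.0619) or male smoke 3 (0.0665), and the neuron and glia call without female air 2 (0.0846), female air 3 (0.0975), female air 4 (0.0614), female smoke 1 (0.062), female smoke 3 (0.102), male air 3 (0.0898), male smoke 1 (0.0646) or male smoke 4 (0.142). The FGF and EGF call was lost without female air 1 (0.109), female air 2 (0.084), female smoke 2 (0.0877), female smoke 3 (0.0727), male air 1 (0.0709), male air 3 (0.086), male air 4 (0.0712), male smoke 1 (0.0646), male smoke 2 (0.0578) or male smoke 4 (0.0801), and the cytosolic ribosomal call without female air 3 (0.172), female air 4 (0.0891), female smoke 1 (0.155), female smoke 2 (0.0625), male air 1 (0.0747), male air 2 (0.106), male smoke 3 (0.0533) or male smoke 4 (0.278). With the same total, the calls of ABC transporters, autophagy and the FGF and EGF pathway were lost (0.0649 each), the last also with the same upper quartile (0.0525). A replicate block ended the calls of ABC transporters (0.0696) and of neuron and glia markers (0.0764). Fry did not call autophagy (fry adjusted p = 0.0654), the FGF and EGF pathway (0.111) or cytosolic ribosomal proteins (0.383). Nor did it call muscle (0.510) or neuron and glia markers (0.287).

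In all, the difference passed an adjusted p of 0.05 in limma for 187 of 8606 genes, 172 more positive and 15 more negative in females. The split depended on the fit, with 242 and 123 with the naming-style batch as a term, 237 and 86 with array weights, 262 and 80 with DESeq2, 155 and 23 with the same upper quartile, and 163 and 8 with edgeR. With a replicate block, whose counts are given below, more positive genes no longer outnumbered more negative ones. The labels do not say that the replicate numbers pair the samples. Serial numbers in some column names run close together within a replicate number, across sexes and treatments, so pairing by number stays open. Of 41 lists, 21 were called by limma camera, 7 by fry, and none with an estimated correlation, where 7 had an unadjusted p under 0.05. The fold change was above 0 in females and below 0 in males for 154 of the 187 genes and the reverse for 10, and 62 were called both higher in females and lower in males. Without male air 4 the count was 124, and without male air 3 it was 154. The 15 more negative genes became 8 without female air 4, 9 without female smoke 3 and 7 without male air 1 or male air 4. All 187 differences had the same sign within replicates 1 and 2 and within replicates 3 and 4, although these libraries also chose the genes.

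Responses were also compared for their direction. Of 2114 genes called in either sex 1827, or 86.4%, had the same sign in both. Genes higher in both sexes numbered 495, against 85.9 expected of independent lists (one-sided Fisher's exact test, log10 p = -324.25), and they included Prx2540-2, dyl, Hsp26, stv, puc, rpr and Thor. Genes lower in both numbered 62 against 28.03 expected (Fisher's exact p = 1.48e-09), and genes higher in females and lower in males also numbered 62, against 44.6 expected (Fisher's exact p = 0.00406). None was lower in females and higher in males by limma or edgeR, against 54.02 expected, while DESeq2 gave 1 and an unadjusted p under 0.05 gave 6. Fisher's test takes genes as independent, which they are not. Across genes the log2 changes of the sexes correlated with Pearson r = 0.447 and Spearman rho = 0.580, and 16 of 100 drawn pairs of splits of the libraries, the real one included, gave an absolute r as large. Within replicates 1 and 2 alone r was 0.319 and within replicates 3 and 4 it was 0.511. The number higher in both was 294 without male air 2, 279 without male smoke 1 and 320 without male smoke 4, and 322 with the same upper quartile. The number lower in both was 121 without female air 2, 24 without male air 2 or male smoke 1, 40 without male air 1, 38 without male air 3, 30 without male air 4, 33 without male smoke 3, 32 without male smoke 4, and 157 with the same upper quartile. Both numbers were larger with the naming-style batch as a term or with a replicate block, as given below. DESeq2 gave 699 higher and 195 lower in both.

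The authors' deposited tables of their own comparison list 681 genes higher and 602 lower in female smoke, and 429 higher and 1156 lower in male smoke, each with an absolute log2 change of at least 0.59 and an adjusted p of at most 0.0994 and 0.0996. Of the genes listed in the authors' deposited tables, 640 higher and 482 lower were tested here in females, and 541 and 253 of these were called in the same direction. In males 414 and 774 were tested, and 330 and 311 were called in the same direction. None was called in the opposite direction. Across genes the log2 changes of the authors' deposited tables and of the limma fit correlated with r = 0.927 in females and 0.953 in males.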

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

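The tests of wrong labels, posterior spiracle, reads from male air 3, salivary carry-over and ecdysone stage were chosen after the results were seen, as were the bound used for the salivary test and the posterior spiracle list. The test of a varying cell population and the rule for libraries far from their group were set before their values were seen.

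Responses differed between the sexes for 33 named genes by the limma test of the difference itself, given here as female minus male log2 change. Differences above 5 were 7.99 for Cpr92F, 6.64 for Cyp4d20, 5.68 for Ugt36E1, 6.68 for ADPS, 8.25 for CG13043, 8.75 for CG8736, 8.29 for Cpr100A, 6.31 for Cpr56F, 10.13 for Cpr62Bc, 6.11 for Cyp313a5, 5.98 for Cyp4c3, 8.37 for Elo68alpha, 8.39 for Elo68beta, 5.99 for GstD8, 7.11 for CG4000, 7.77 for lncRNA:CR43452. Smaller positive differences were 3.57 for Cyp6a20, 0.49 for Gasp, 1.30 for ImpL2, 0.71 for snu, 0.99 for ATPCL, 3.28 for Cda5, 0.78 for crq, 4.65 for Lsd-1, 2.97 for Wnt6, 1.26 for Agpat3. Negative differences were -0.46 for fz4, -0.51 for CG1142, -0.62 for ec, -0.54 for Grip71, -0.47 for Prat, -0.37 for Prp40, -0.46 for Rrp45. The Prp40 call was lost with libraries rescaled to the same total (limma adjusted p = 0.0698), and its adjusted p was at most 0.0416 under all its other settings.

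Genes called lower in male smoke and higher in female smoke numbered 62, with median log2 changes of -2.96 in males and 1.40 in females. Wrong sex labels are argued against by roX1, whose lowest male library stood 5.80 times above the highest female one. For Prx2540-2 the lowest smoke library stood 17.3 times above the highest air one. That gene was chosen as one of the largest rises under these same labels, so its ratio cannot decide whether treatment labels are wrong. Loss of the posterior spiracle from the male smoke samples cannot be told apart from the other explanations. The 5 spiracle genes had a median male log2 change of -0.16 (SD 0.0683), which by the rule first set argued against a loss. After the values were seen the rule was extended to require that no member be called more positive in females, so this stays open. The level of these genes from other cells could hide a loss. Their sum went from 513 to 604 CPM in females and from 557 to 473.3 in males. Abd-B was called higher in females (0.58 ± 0.10, limma adjusted p = 0.00725) and different between the sexes (0.76 ± 0.17, 0.0315). The gene ct was called higher in females (0.57 ± 0.14, 0.0241) but not different between the sexes (limma adjusted p = 0.146). In males neither Abd-B (-0.17, limma adjusted p = 0.413) nor ct (-0.06, 0.795) was called. The others were not called: ems, salm and grn changed by -0.43, -0.21 and 0.13 in females and by -0.11, -0.24 and -0.16 in males. A varying amount of 1 cell population stays open: within groups, with male smoke left out, the 62 genes had a median pairwise correlation of 0.226, against a 95th percentile of 0.0329 and a highest of 0.115 over 1000 gene sets matched on mean. Shared regulation of the genes would give the same, and a sex difference in the response to smoke, which the design names, stays open as a hypothesis.

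Salivary glue genes named Sgs, 7 of them measured, fell in female smoke. Reads from the glue-rich library male air 3 counted in female libraries would keep 1 ratio for all glue genes, and the ratio of female air to that library ran from 0.597% to 6.83%, a spread of 11.4 times that argues against it. Salivary gland tissue carried over with the trachea may explain the fall. The 4 salivary markers tested besides the Sgs genes had a median log2 change of -1.86 (SE 1.02), which met the bound of -1 first set. After the value was seen the bound was tightened to pass -1 by more than the SE, which the median did not, so carry-over stays open. These 4 were Eig71Ee (-4.19), fkh (-1.91), ng3 (-1.80) and sage (-0.23), and only Eig71Ee passed the limma test. By their names ng3 (new glue 3) is itself a glue gene and Eig71Ee is ecdysone-induced. Their median therefore cannot separate carried-over tissue from a change in glue gene expression. A different stage of the ecdysone response also stays open: the ecdysone list was not called as deposited (limma camera adjusted p = 0.0912, median log2 change 0.27), but it was with the same upper quartile (0.0322) or total (0.0324), and its members moved both ways.

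A library far from the other 3 of its group, with a gap to the nearest that passed Dixon's critical share of the group's range on the log2(value + 1) scale, appeared in 26 of 386 groups tested, where chance gives 19.3. In female air these were, for replicate 3, CG12896 at 45.4 (2.21 to 3.87 in the others), EcR at 5018 (6017 to 6236 in the others), Prx2540-1 at 66.8 (7.67 to 10.1 in the others), Sgs4 at 105 (326 to 355 in the others) and twz at 55.5 (196 to 253 in the others). For female air replicate 2 they were MtnE at 9.20 (19.3 to 22.1 in the others), pyr at 320.4 (509 to 512 in the others) and upd2 at 42.2 (9.28 to 11.04 in the others). Sex determination markers stood at 809 CPM in female air replicate 1, against 627 to 651 in the others. In female smoke they were Cyp6a20 at 171 in replicate 4 (79.1 to 83.4 in the others), Gasp at 21053 in replicate 1 (19498 to 19652 in the others) and ec at 2376 in replicate 2 (2659.8 to 2713 in the others), and fat body markers at 5807 CPM in replicate 3, against 1275 to 1575.

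Among male air libraries they were Hsp70Aa at 1.27 in replicate 3 (0 in the others), Rel at 3279.9 in replicate 1 (2163 to 2302 in the others), ADPS at 417 in replicate 4 (67.4 to 79.4 in the others), Agpat3 at 2842 in replicate 4 (2479.5 to 2499 in the others) and CG4000 at 1704 in replicate 3 (3454 to 3691 in the others). Marker sums CPM stood apart in male air replicate 3 for salivary gland (7840 against 14.5 to 38.04) and hemocytes (3104 against 1311 to 1396). In male smoke they were Hsp70Bc at 261 in replicate 3 (670.5 to 787 in the others), ref(2)P at 5339 in replicate 2 (6577 to 6671 in the others), Cpr100A at 115.1 in replicate 3 (40.98 to 47.5 in the others), Elo68alpha at 96.3 in replicate 2 (0.97 to 2.65 in the others) and Kr-h1 at 766 in replicate 3 (1069 to 1128 in the others), and Y-linked genes at 0.664 CPM in replicate 4, against 0.200 to 0.258 in the others.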

How the results depend on the processing

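The naming-style batch term, the fits within replicates 1 and 2 or 3 and 4, and list tests at the same total were chosen after the results were seen, and the other settings were planned. Counts are genes called by limma at an adjusted p under 0.05 unless another tool is named, and a count that differed from the reported one by over 1.5 times is given with its setting. Where none is stated, the cause was not tested.

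Pseudocounts of 0.5 and 5, no filter and a filter of 50 moved no count by over 1.5 times (females 1377 to 1621, males 1091 to 1188, sex difference 153 to 212). Rescaling moved directions: with the same upper quartile 1201 genes were lower in females, 459 higher in males, 23 more negative in the sex difference, and 322 higher and 157 lower in both sexes with 88.1% of the same sign. With the same total 644 were higher and 1042 lower in females, and 444 higher in males. Array weights gave 2906 genes in females (1557 higher, 1349 lower) and 323 for the sex difference (86 more negative). DESeq2 gave 997 lower in females, 1971 in males (878 lower) and 342 for the difference (262 and 80), and edgeR 8 more negative for the difference. Across the sexes DESeq2 gave 195 genes lower in both and 95 higher in females and lower in males. DESeq2 made more false calls than limma on simulated data. A minimum fold of 2 left, by construction, 426 in females (292 higher, 134 lower), 420 in males (149 higher) and 0 more negative genes in the difference.

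With a replicate block, counts rose to 2504 in females (1130 lower), 2816 in males (1669 higher, 1147 lower) and 817 for the difference (405 and 412), with 1541, 1163 and 187 of the reported genes kept, and to 909 higher and 287 lower in both sexes with 82.6% of the same sign. The labels do not say that the numbers pair the samples. Serial numbers in some column names do run close together within a replicate number, across sexes and treatments. Correlations of deviations between same-numbered smoke and air libraries were 0.171, 0.289, 0.421 and -0.0977 in females and 0.376, 0.0383, 0.371 and 0.463 in males. Smoke libraries correlated best with the air library of their own number except female 4 and male 2. Pairing by number therefore stays open, and the main tests, fitted without the block, do not allow for it. The block ended the call of the metal response in males (camera adjusted p = 0.0696 with limma) and of ABC transporters (0.0696) and neurons and glia (0.0764) in the difference.

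Naming batch as a term gave 2514 genes in females (1115 lower), 1967 in males (1242 higher, 725 lower), 365 for the difference (123 more negative), and 748 higher and 171 lower in both sexes with 83.9% of the same sign. Within replicates 1 and 2, where fewer samples entered, limma called 12 genes in females (12 higher, 0 lower, against 678 lower at an unadjusted p under 0.05) and 146 in males (87 higher, 59 lower). Within replicates 3 and 4 it called 799 in females (567 higher, 232 lower) and 11 in males (6 higher, 5 lower). Between the sexes r was 0.319 and rho 0.477 within replicates 1 and 2, with 5 genes higher and 0 lower in both and 70.2% of the same sign. Within replicates 3 and 4 r was 0.511, with 6 higher and 0 lower in both and 91.0% of the same sign.

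Leaving out 1 library gave 994 to 1998 genes in females (648 to 1154 higher, 342 to 844 lower), 478 to 1156 in males (340 to 705 higher, 138 to 451 lower) and 124 to 185 for the difference (117 to 174 and 7 to 17). Between the sexes r ran from 0.352 to 0.541, rho from 0.493 to 0.614, genes higher in both from 279 to 525, lower in both from 24 to 121 and the same sign from 84.0% to 89.5%. Lists called ran from 16 to 22, 17 to 22 and 17 to 22. Named genes lost their call in 23 of 552 such fits in females, 54 of 572 in males and 0 of 192 for the difference. Lists called with an estimated correlation were 0, 0 and 0, at smallest adjusted p-values of 0.299, 0.430 and 0.183 (camera of limma), and fry called 7 for the difference.

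Among the named genes and called lists, only the dosage compensation RNAs, neither called in males, turned their sign in any setting run. For lncRNA:roX1 in males (reported 0.02) the log2 change was -0.0639 with the same upper quartile, -0.0517 with the same total, -0.0230 with edgeR and -0.0186 with DESeq2, and -0.07, -0.14, -0.10 and -0.02 without male air 3, air 4, smoke 1 and smoke 2, in a range of -0.14 to 0.15 over the fits that left out 1 library. For lncRNA:roX2 in males (reported -0.16) it was 0.0326 without male air 2, in a range of -0.34 to 0.0326. Depth was not varied. On simulated data limma recovered 5.97% of 1.5-fold changes in females and 14.9% in males. Of 2-fold changes it recovered 36.1% below and 71.0% above the median level of the changed genes in females, and 37.9% and 60.5% in males.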

Other observations

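Of the tests here, the imaginal disc list, the test of scaling and the relabellings balanced over the naming-style batch were chosen after the results were seen, and the others were planned. Other gene groups moved in part. Of 20 TGF-beta and BMP pathway genes 4 rose in each sex, against 4 and 5 adjusted over the list alone, and 3 fell in females and none in males. Neither list was called (limma camera adjusted p = 0.482, and adjusted p = 0.858 with an estimated correlation in females). In males, limma camera adjusted p = 0.0538, and adjusted p = 0.471 with an estimated correlation. Dad, which encodes an inhibitory Smad, rose by 1.15 ± 0.12 in females and 1.63 ± 0.16 in males on the log2 scale, and shn by 1.00 ± 0.10 and 0.97 ± 0.12. Of 18 unfolded protein response genes 4 rose in females and 3 in males, also adjusted over the list alone, with the sensor kinase genes Ire1 at 1.12 ± 0.11 and 0.89 ± 0.10 and in males PEK at 0.68 ± 0.05. That list was not called (limma camera adjusted p = 0.0869 in females and 0.377 in males, where its median of -0.04 and mean of 0.21 differ in sign). Of 24 ecdysone response genes 4 rose and 1 fell in females and 7 rose and 1 fell in males, against 5 and 1 and 7 and 1 adjusted over the list alone (limma camera adjusted p = 0.0912 and 0.23, with a male median of 0.06 and mean of -0.12). The female list passed with the same upper quartile (0.0322) or total (0.0324). The receptor gene EcR rose by 0.66 ± 0.10 in females, and Kr-h1, a juvenile hormone response gene, by 1.28 ± 0.18 in males.

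Of 32 tracheal identity and tube genes measured in females 5 rose and 3 fell, against 7 and 4 adjusted over the list alone, and of 31 in males 5 rose and none fell, against 6 (limma camera adjusted p = 0.722 and 0.268). In females dyl rose from 16.1 ± 6.64 to 838 ± 412. Of 33 Wnt pathway genes 8 fell and 4 rose in females, against 10 and 6 adjusted over the list alone, including the receptor genes otk2 (-1.35 ± 0.20) and fz4 (-0.48 ± 0.08), and the list was not called (limma camera adjusted p = 0.178). The list of antimicrobial effectors was not called, with none of 14 genes passing in females by limma, edgeR or DESeq2 or at an unadjusted p under 0.05. In males 1 of 20 was lower by limma, also adjusted over the list alone, 2 were lower by edgeR, 2 higher and 5 lower by DESeq2, and 1 higher and 5 lower at an unadjusted p under 0.05 (limma camera adjusted p = 0.737 and 0.373). Cyp6g1, a P450 gene known from insecticide resistance, did not pass the limma test (log2 change -1.32 ± 0.58 in females and -2.80 ± 1.06 in males, adjusted p = 0.152 and 0.113). With DESeq2 it did (adjusted p = 0.0388 and 0.016), and over all other settings its adjusted p lay between 0.0184 (without female air 2) and 0.319 in females and 0.00901 (with a replicate block) and 0.247 in males. It also passed in males in limma with the naming-style batch as a term (0.0429).

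Of 36 cell cycle genes 18 fell in female smoke (limma camera adjusted p = 0.357 with an estimated correlation). The list stayed called lower under both other scalings of the libraries (limma camera adjusted p at most 2.04e-08). Camera compares a list with other genes. Both scalings also lowered the median log2 change of all genes in females, from -0.018 to -0.126 and -0.133. The list was therefore unlikely to lose its call, and this test cannot decide whether the authors' scaling added to the fall. Imaginal disc tissue carried over with the trachea may account for part of the fall: over the 16 libraries, deviations from the group means of the cell cycle score (36 genes) and of the disc score (17 genes) correlated with r = 0.742 and rho = 0.774 (one-sided permutation p = 0.00223 and 0.00132 over 100000 permutations within groups), with r = 0.716 in females, 0.786 in males, 0.596 in replicates 1 and 2, 0.882 in replicates 3 and 4 and 0.651 without the 2 farthest libraries. The slope of that relation gives -0.26 of the fall of -0.54 in females, and in males the disc score changed by -1.74 while the cell cycle score changed by -0.04. A lower cell cycle activity of the female trachea itself stays open as a hypothesis.

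Other splits of the same libraries show which results exceed chance. The real split gave the most called genes of the 35 splits in females (1 of 35 as large, itself, with 1599 against at most 269) and in males (1 of 35, with 1178 against at most 467). After the mean of each sex was taken out of each gene, 2 of 100 relabellings of sex within treatment, the real one included, gave as many as the 187 genes of the sex difference (highest other 391). These shares, each under 0.05, make chance unlikely for the 3 counts, although with 35 splits no share can be below 1 of 35. The relabelling that gave 391 genes put smoke replicates 1 and 2 against smoke replicates 3 and 4, as the naming-style batch does. The highest other split of each sex followed the naming-style batch, and a fit with that batch as a term called 2514 genes in females and 1967 in males. With the real split counted in, chance cannot be excluded for the number of lists called in females (2 of 35 splits, 19 against at most 19) and males (5 of 35, 20 against at most 25), and is unlikely for the difference (4 of 100, 21 against at most 24). For the correlation of the fold changes between the sexes it cannot be excluded either (16 of 100 as large, 0.447 against 0.653), nor with splits that put 2 libraries of each naming-style batch in each group (18 of 100 as large, 0.447 against 0.562). These ranks cannot decide the question, because some splits kept structure. One held all male air libraries together, and female air 1, 3 and 4 with female smoke 4 (absolute r 0.538). A balanced one grouped replicates 1 and 3 in both sexes (0.558).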
